A study of Mus musculus with 4 samples.

How the data were processed

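RNA from intestinal epithelial cells of tamoxifen-treated mice was measured on 4 Illumina mouse bead arrays, 2 per group. Per the labels' protocols, tamoxifen was given at 120 mg/kg on consecutive days, and cells were released from the middle of the small intestine 5 days after the last injection, by 30 min in cold (4 °C) buffer with 5 mM EDTA. Per the labels' protocols, RNA came from a column kit that keeps small RNAs and was turned into biotin-labelled cRNA. The protocol writes the same Ifnar1+/+ genotype for both crosses, so the groups were taken from the sample titles, which fit the genotype labels. All arrays lay on 1 chip, so there was no batch to test, but the position on the chip follows the group.

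The deposited raw intensity values are the mean bead signal per probe, exported with GenomeStudio 1.8 per the submitters' processing notes, with no background subtracted and no scaling between arrays. The deposited detection p-values compare each signal with negative controls whose own signals were not used here. The deposited normalized intensity values have the same lowest (93.1) and highest (57820.3) value on every array and medians of 149.4 to 149.6. They are linear and not background subtracted, and each array's Spearman correlation with its own raw signals was 0.999999, against at most 0.912 with those of another array. How they were scaled is not given in the sources used here. Raw signals had medians of 145.3 and 143.5 on the Ifnar1+/+ arrays and 157.8 and 151.3 on the Ifnar1-/- arrays.

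Raw intensities were corrected for background, quantile normalized and put on a log2 scale with neqc of limma 3.58.1 in R 4.3.3, the background being estimated from the detection p-values, with an offset of 16. The offset pulls the fold changes of dim genes toward 0. Probes with a detection p under 0.05 on at least 2 of the 4 arrays were kept, which left 11884. Gene symbols came from the platform annotation: 23978 probes had 1 symbol, 0 had several and 1719 had none. Of these probes, 23962 were found in the RefSeq gene table, which changed 0 symbols and served otherwise only to say which genes neighbour each other. The genome build behind the probes is not given in the sources used here, so no coordinates are printed. The brightest kept probe stood for each gene, giving 8442 genes. Of the 2009 genes with several kept probes, 34.5% had probes that disagreed in direction. A gene not above background on every array of a group has only a bound there, and "at least N-fold" sets the brighter group's mean against the lowest signal well above background on the dimmer group's arrays, or the probe's own if higher. The fold compares means of normalized log2 values.

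Groups were compared with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment over all genes and, for each fixed list, over the list alone. All 4 arrays entered the fit with no covariate, leaving 2 residual degrees of freedom and a prior of 4.56. Differences are Ifnar1-/- minus Ifnar1+/+. Lists with at least 4 tested genes were compared with the other genes by camera at a preset correlation of 0.01, adjusted over the 32 lists; the statmod package (1.5.0) was used with limma. Lists cover interferon responses, MHC genes, crypt and villus cell types, other cells that a preparation can hold, metabolism, stress, gut regions and the neighbours of Ifnar1. Named genes are the receptor genes, Csnk1a1 and sex-linked genes, 10 genes per direction, and the 3 members of each list with the smallest p. As no gene passed, the 10 were filled by smallest p among non-overlapping genes with a log2 difference of at least 1. The design, the lists, this rule and all alternatives but 1 were fixed before the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

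The alternatives were no background correction, an offset of 50, median scaling, the deposited normalized values, no filter, a detection p under 0.01 on all arrays, the mean of a gene's probes, an intensity trend, robust moderation, array weights, an adjusted p under 0.1, the replicate number as a block, each array left out, an estimated correlation and fry. With an array left out, the group of 1 array is assumed to vary like the other. Tested on 20 simulated data sets of 8442 genes drawn with the spread of these arrays, with 200 genes changed in each, the limma fit recovered 4.24% of changes of 1 log2 unit, 81.9% of changes of 2 and 96.5% of changes of 3, with 5.65 false calls per set. A list of 30 genes lowered by 1 log2 unit was called by camera in 20 of the 20 sets, and in 0 with an estimated correlation. Simulated genes varied independently. The correlation estimated from the real arrays was 0.31 for interferon-stimulated genes, 0.86 for absorptive enterocyte genes and -0.02 for endoplasmic reticulum stress genes. The simulation therefore cannot show how the preset correlation behaves on lists whose genes vary together.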

Results

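Gene expression was measured in intestinal epithelial cells of C57BL/6 mice on 4 single-colour Illumina bead arrays, each with 25697 probes. In both groups of mice Csnk1a1 had been deleted from the gut epithelium with a tamoxifen-activated Cre recombinase under the villin promoter. Csnk1a1 encodes casein kinase 1 alpha, a kinase that marks beta-catenin for destruction. The groups differed in Ifnar1, which encodes a chain of the receptor for type I interferons: 2 arrays came from Ifnar1+/+ samples and 2 from Ifnar1-/- samples. The titles call the first group wild type, but its genotype label carries the Csnk1a1 deletion too, so the comparison is within Csnk1a1-deleted epithelium. The labels give the tissue as colon, whereas the protocol takes cells from the middle of the small intestine. Of the fixed small intestine genes with a probe, 12 of 18 were detected on every array and 4 on none; of the fixed colon genes, 8 of 23 were detected on every array and 11 on none. Detected probes numbered 11700 and 11234 on the Ifnar1+/+ arrays and 11954 and 11391 on the Ifnar1-/- arrays, and the number of arrays limits the precision. The labels do not say whether the samples of a group came from separate animals. The p-values of single genes therefore measure only the spread between these samples, which may be technical. List p-values from camera at the preset correlation compare a list's genes with the other genes. They rest largely on the spread over genes and allow little for genes that vary together.

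The probe for Ifnar1 was not well above background on any of the 4 arrays, with signals of 119.3 to 135 and detection p-values of 0.301 to 0.902. Its normalized log2 intensity was 4.69 ± 0.22 (SD, n = 2) in the Ifnar1+/+ group and 4.54 ± 0.12 (SD, n = 2) in the Ifnar1-/- group. The probe for Csnk1a1 was likewise not well above background, at 4.73 ± 0.21 and 4.64 ± 0.01 (SD, n = 2 each). Neither probe therefore checks the genotype labels. Ifnar2, which encodes the other chain of the receptor, differed by -0.06 ± 0.33 (log2, SE), and the difference was 0.36 without Ifnar1+/+ array 1 and 0.03 without Ifnar1-/- array 2. The Y-linked genes Eif2s3y, Kdm5d and Uty were detected on all 4 arrays, and Xist, the RNA that silences the second X chromosome, on none. Their log2 differences were 0.42 ± 0.24, 0.01 ± 0.23 and -0.15 ± 0.22 (SE), and that of Kdm5d was -0.09 without Ifnar1-/- array 1.

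The series title concerns type I interferons and the intestinal epithelium, and the comparison of Ifnar1-/- with Ifnar1+/+ cells addresses this in the absence of Csnk1a1. Interferon-stimulated genes were lower in the Ifnar1-/- samples: 32 of 33 had a lower mean, and the median gene was 2.01-fold lower. Markers of T cells and intraepithelial lymphocytes and genes of absorptive enterocytes were also lower, with median genes 2.28-fold and 1.72-fold lower. Cell cycle genes had a higher mean in 28 of 28 cases, by a median of 1.44-fold, though 0 passed when adjusted over the list alone. Their log2 median was 0.77 on Ifnar1-/- array 1 and 0.27 on array 2. Paneth cell genes had a higher mean in 10 of 10, by a median of 2.14-fold, chiefly on 1 of the 2 Ifnar1-/- arrays. Of 33 lists fixed before the data were examined, 32 were tested and 22 passed the threshold of limma's camera, 4 with higher and 18 with lower values. With a correlation estimated from the arrays no list passed, the smallest adjusted p being 0.41 with an estimated correlation. That test also called 0 of 20 simulated lists lowered by 1 log2 unit, so its lack of calls cannot tell a changed list from an unchanged one. When the 4 arrays were split so that each side held 1 array of each genotype, 8 and 12 lists passed. Medians of lists that hold dim genes shrank by over 1.5 times without background correction or without a filter, as given beside the larger lists.

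**Figure D1:**
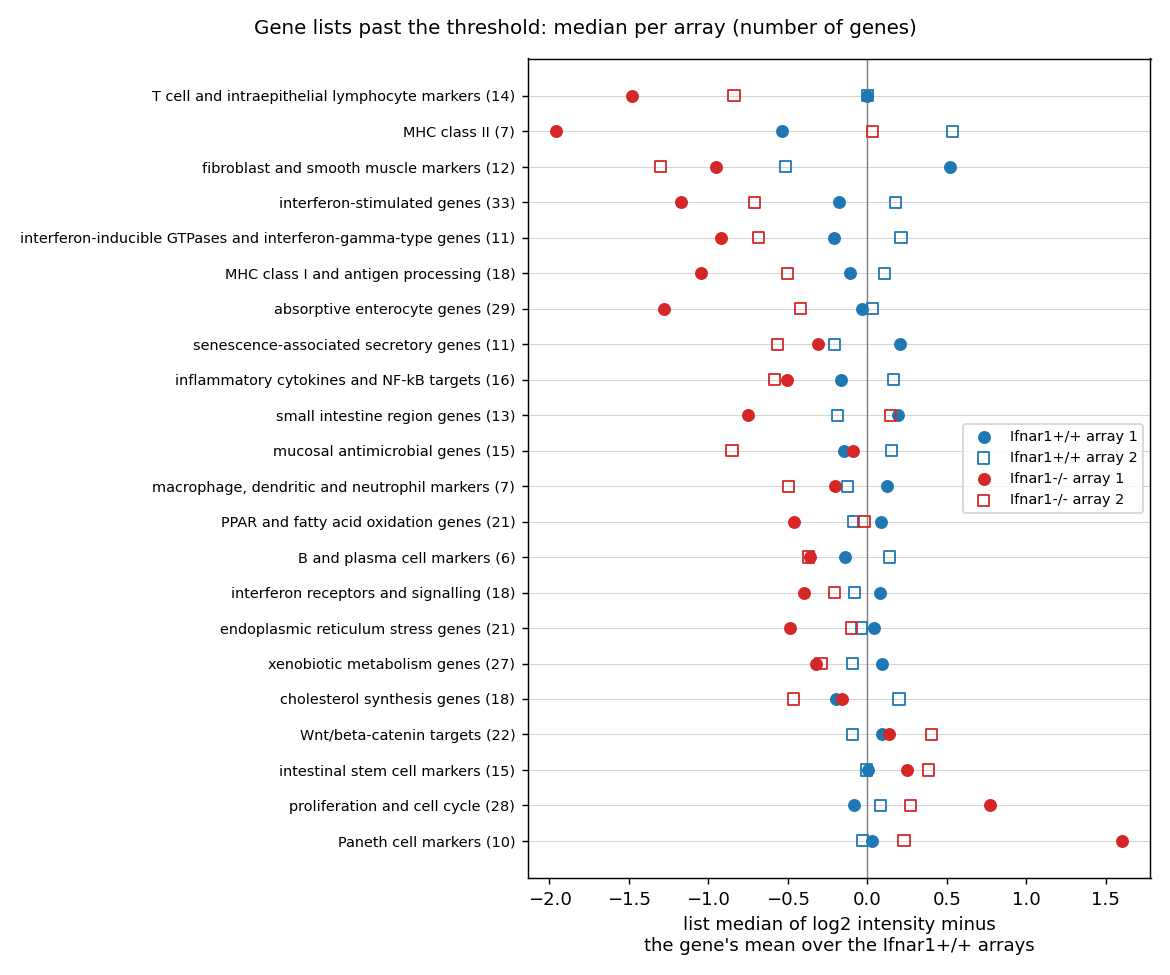
Median over each list of normalized log2 intensity minus the gene's mean over the Ifnar1+/+ arrays (x axis, log2 units), for the 22 lists past the threshold (y axis, with the number of genes tested); blue marks are the Ifnar1+/+ arrays and red marks the Ifnar1-/- arrays, filled circles array 1 and open squares array 2. Interferon-stimulated genes lie at -1.18 and -0.71 on the Ifnar1-/- arrays, and Paneth cell markers at 1.60 on array 1 and 0.23 on array 2.

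Among 8442 genes tested singly, limma called 0 higher and 0 lower at an adjusted p under 0.05, and 0 under 0.1; the smallest adjusted p was 0.29. At an unadjusted p under 0.05 there were 360 higher and 445 lower genes, or 9.54% of those tested. The values of the 2 groups did not overlap for 3661 genes, or 43.4%. Averaged over the 3 splits of 4 arrays into pairs, this share is 33.3%. Genes can vary together and the shares of the other splits were not counted, so 43.4% cannot be read as an excess over chance. The gene with the smallest p was Oas2, an interferon-induced enzyme that senses double-stranded RNA, with a log2 difference of -2.35 ± 0.24 (SE, n = 2 per group). It was not well above background on either Ifnar1-/- array and was at least 4.21-fold lower there. Ifnar1-/- array 1 stood apart from the other arrays. It differed from Ifnar1-/- array 2 by more than 1 log2 unit in 621 genes (7.36%), whereas the Ifnar1+/+ arrays differed by as much in 142 genes (1.68%). Without Ifnar1+/+ array 1, 5 genes passed, each of them lower: Pla2g4c, Prss27, Isg15, B3galt5 and Oas2. Without Ifnar1+/+ array 2, the lower genes included Oas2 (-2.26), Dcn (-2.82), Vim (-2.46), Sparc (-2.44) and Col6a1 (-2.22), and B3galt6, Adat2 and Gm5801 were higher. Apart from Oas2, the lower genes named for that fit belong to the fibroblast and smooth muscle list. Its median was 0.52 on Ifnar1+/+ array 1, the array kept, and -0.52 on array 2. Apart from Oas2, Vim and Sparc, the genes named for fits with an array left out were chosen after their values were seen.

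Interferon-stimulated genes had a median log2 difference of -1.01 (quartiles -1.41 and -0.54). Of the 33 measured, 18 were lower when adjusted over the list alone, none was higher, and 0 passed over all genes tested. After Oas2, the smallest p-values belonged to Usp18, a protease that removes ISG15 from proteins and dampens receptor signalling (-1.73 ± 0.26, SE), and Parp14, a mono-ADP-ribosyltransferase (-1.77 ± 0.27). The list passed camera with an adjusted p = 1.2e-20, and had an adjusted p = 0.41 with an estimated correlation. Its median was -1.18 on Ifnar1-/- array 1 and -0.71 on array 2, and without background correction it was -0.48. With the 2 members not above background set at their bounds the median was -0.94. Oasl2, a relative of the oligoadenylate synthetases and 1 of the 10 named lower genes, differed by -2.04 ± 0.33.

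Other groups tied to interferon were lower as well. Of 11 interferon-inducible GTPases and interferon-gamma-type genes, 6 were lower when adjusted over the list alone, with a list median of -0.80 and an adjusted p = 3.6e-07 (adjusted p = 0.41 with an estimated correlation). The GTPase genes Irgm2 and Igtp differed by -1.84 ± 0.31 and -2.02 ± 0.39 (SE), and Ido1, which degrades tryptophan, by -1.31 ± 0.30. This median was -0.35 without background correction and -0.22 with no filter on dim probes. Of 18 genes of MHC class I and antigen processing, 5 were lower when adjusted over the list alone; the median was -0.79, the adjusted p = 8.5e-10, and the adjusted p = 0.41 with an estimated correlation. They included the class I heavy chain H2-K1 (-1.37 ± 0.27), the peptide transporter Tap1 (-1.06 ± 0.24) and Nlrc5, a transcriptional activator of class I genes that was not well above background on the Ifnar1-/- arrays and at least 2.54-fold lower. Without Ifnar1-/- array 1 the class I median was -0.49. The 18 interferon receptor and signalling genes had a median of -0.34 (adjusted p = 0.0026; adjusted p = 0.41 with an estimated correlation), with 17 lower and 0 passing over the list alone. In this list Socs3, a feedback inhibitor of cytokine signalling, differed by -1.41 ± 0.38, Stat2 by -0.55 ± 0.28 and the phosphatase gene Ptpn6 by -0.49 ± 0.24. The call was lost without Ifnar1-/- array 1 (median -0.21, adjusted p = 0.059) and with members shared with other lists left out (-0.11, adjusted p = 0.088).

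Of the lists of markers of other cells, those of T cells and of fibroblasts and smooth muscle also passed as lower. All 14 T cell and intraepithelial lymphocyte markers were lower, 11 of them when adjusted over the list alone, with a median of -1.19. The adjusted p was 7.2e-13, and the adjusted p = 0.41 with an estimated correlation. Cd3g and Cd3d, which encode chains of the T cell receptor complex, differed by -1.90 ± 0.41 (SE) and -1.33 ± 0.22, and Nkg7, a granule protein of cytotoxic lymphocytes, by -1.43 ± 0.27. Cd3d was not well above background on either Ifnar1-/- array, at least 1.71-fold lower. The list median was -1.48 on Ifnar1-/- array 1 and -0.84 on array 2, against 0.00 on both Ifnar1+/+ arrays, and it was -0.54 without background correction and -0.41 with no filter on dim probes. Fibroblast and smooth muscle markers (12 genes, 10 lower and 2 higher, 0 passing over the list alone; median -1.09, adjusted p = 0.00023; adjusted p = 0.51 with an estimated correlation) were unequal between the Ifnar1+/+ arrays, at 0.52 and -0.52. Among them were the collagen gene Col6a2 (-1.24 ± 0.35), the matrix protein gene Sparc (-1.57 ± 0.54) and the intermediate filament gene Vim, at least 1.99-fold lower. Vim lay at 7.16 and 5.38 on the Ifnar1+/+ arrays, so its bound rests chiefly on array 1. Its difference was -0.59 without Ifnar1+/+ array 1 and -2.46 without Ifnar1+/+ array 2. That list's median was -0.32 without Ifnar1+/+ array 1 and -1.60 without array 2, and its call was lost without Ifnar1-/- array 2 (-0.95, adjusted p = 0.090).

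The remaining immune lists were smaller and rested on single arrays. The 7 MHC class II genes had a median of -1.15 (adjusted p = 0.0074; adjusted p = 0.53 with an estimated correlation), with -1.96 on Ifnar1-/- array 1 and 0.03 on array 2. H2-DMa and H2-DMb1, which load peptides onto class II molecules, differed by -1.47 ± 0.69 and -1.06 ± 0.55 (SE), and the class II activator Ciita by -1.22 ± 0.64. Their call was lost without Ifnar1-/- array 1 (0.04, adjusted p = 0.82), without Ifnar1+/+ array 2 (-0.48, adjusted p = 0.061) and with no filter on dim probes (-1.01, adjusted p = 0.056), and the median was -1.96 without Ifnar1-/- array 2. Of 7 macrophage, dendritic and neutrophil markers (median -0.37, adjusted p = 0.011; adjusted p = 0.41 with an estimated correlation), 1 passed over the list alone, Laptm5, a lysosomal protein of blood cells (-1.47 ± 0.27); Fcer1g (-0.98 ± 0.50) and Ms4a6d (-0.51 ± 0.38) did not. That call was lost without Ifnar1+/+ array 1 (-0.12, adjusted p = 0.074) and without Ifnar1-/- array 2 (-0.20, adjusted p = 0.16). Of 6 B and plasma cell markers (median -0.36, adjusted p = 0.048; adjusted p = 0.53 with an estimated correlation), 1 passed over the list alone, the B cell receptor chain Cd79b, at least 1.38-fold lower. The B cell list kept its call under 5 of 15 other settings of the preset test, and its adjusted p was 0.46 without Ifnar1+/+ array 2 (median -0.16) and 0.27 without Ifnar1-/- array 2 (-0.37), against 0.017 without Ifnar1+/+ array 1 (-0.58). With its 3 members not above background at their bounds its median was -0.25.

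**Figure D2:**
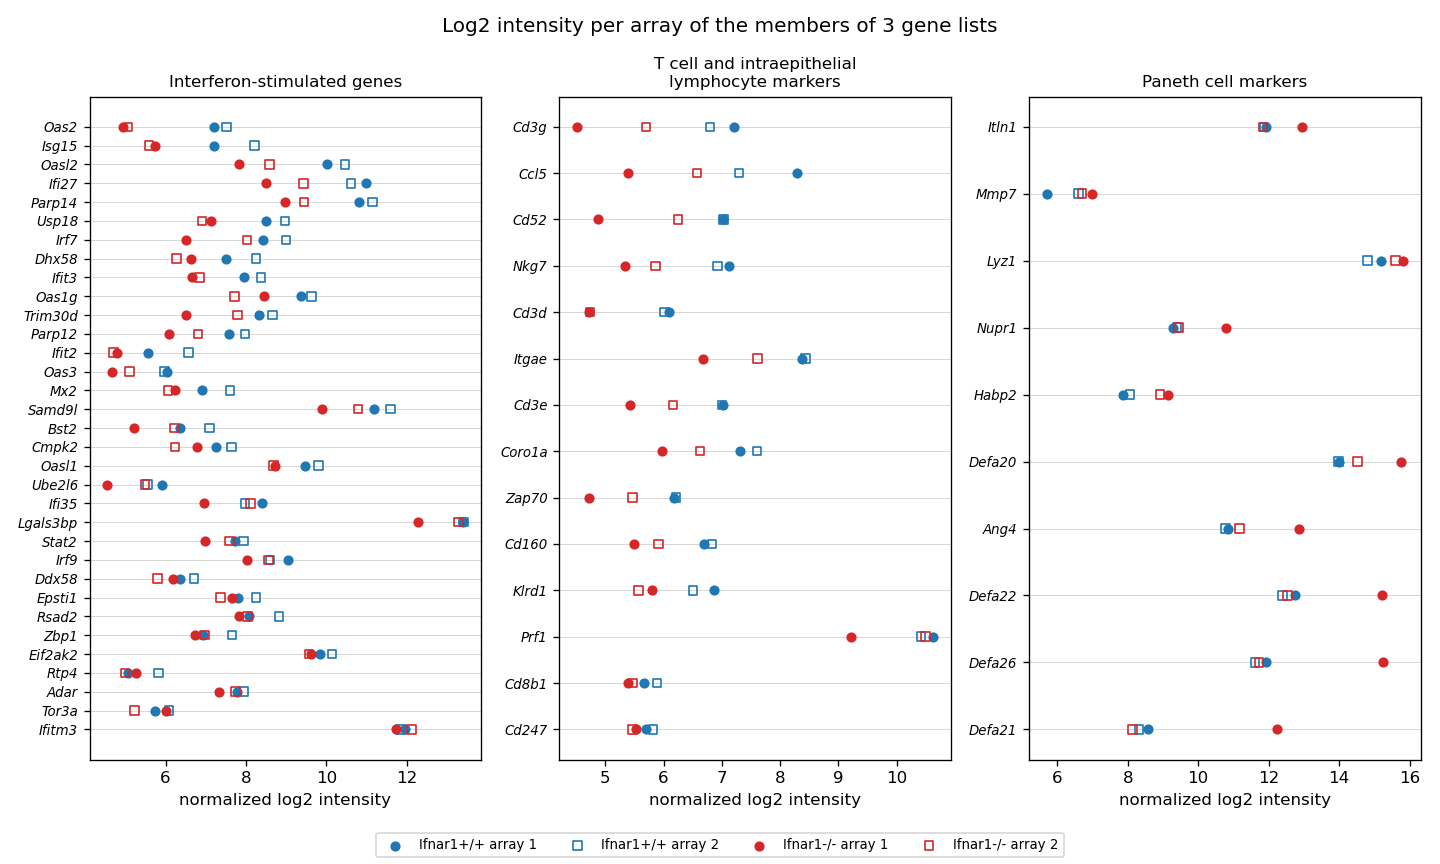
Normalized log2 intensity (x axis) of each tested member (y axis) of the interferon-stimulated gene, T cell and intraepithelial lymphocyte, and Paneth cell lists; blue marks are the Ifnar1+/+ arrays and red marks the Ifnar1-/- arrays, filled circles array 1 and open squares array 2. Oas2 has group means of 7.35 and 5.00, and the defensin gene Defa21 lies at 12.24 on Ifnar1-/- array 1 and at 8.14 on array 2.

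Genes of the absorptive enterocyte, the cell that digests and takes up nutrients, had a median of -0.79, with 28 of 29 lower and 2 lower when adjusted over the list alone. These 2 were the aminopeptidase gene Anpep (-1.86 ± 0.40, SE) and the peptidase gene Ace, not well above background on the Ifnar1-/- arrays and at least 1.84-fold lower; the metalloprotease gene Mep1b followed (-1.08 ± 0.27). The list had an adjusted p = 2.3e-12, and an adjusted p = 0.51 with an estimated correlation. Its median was -1.28 on Ifnar1-/- array 1 and -0.42 on array 2; without array 1 it was -0.41 and without array 2 -1.28. Of 13 small intestine region genes (median -0.43, adjusted p = 0.046; adjusted p = 0.60 with an estimated correlation), 1 passed over the list alone, the ileal bile acid-binding protein gene Fabp6 (-1.72 ± 0.26). The sucrase-isomaltase gene Sis (-0.79 ± 0.27) and the lysozyme gene Lyz1 (0.71 ± 0.25) followed. That list was at 0.14 (adjusted p = 0.74) without Ifnar1-/- array 1, at -0.32 (adjusted p = 0.13) without Ifnar1+/+ array 1, and at -0.75 without Ifnar1-/- array 2; with the strict filter its adjusted p was 0.058.

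Metabolic lists showed small differences. The 27 xenobiotic metabolism genes had a median of -0.17 (adjusted p = 0.011; adjusted p = 0.41 with an estimated correlation) and 20 lower members. Sult2b1, a sulfotransferase gene for sterols, differed by -1.15 ± 0.26 (SE), and the cytochrome P450 genes Cyp2c65 and Cyp2c55 by -1.03 ± 0.35 and -1.12 ± 0.45. This call was lost without Ifnar1+/+ array 1 (-0.11, adjusted p = 0.079) and without Ifnar1-/- array 2 (-0.33, adjusted p = 0.089), and the median was -0.42 without Ifnar1+/+ array 2 and -0.30 without Ifnar1-/- array 1. The 21 PPAR and fatty acid oxidation genes had a median of -0.36 (adjusted p = 0.019; adjusted p = 0.58 with an estimated correlation). Crat, which transfers acetyl groups to carnitine, differed by -0.89 ± 0.24, the peroxisomal thiolase gene Acaa1a by -0.91 ± 0.31 and Eci2, a peroxisomal isomerase gene, by 0.82 ± 0.32. That call was lost without Ifnar1-/- array 1 (-0.02, adjusted p = 0.47) and without Ifnar1+/+ array 1 (-0.29, adjusted p = 0.39). The 18 cholesterol synthesis genes had a median of -0.15 (adjusted p = 0.034 and, with an estimated correlation, adjusted p = 0.60). Tm7sf2 differed by -0.61 ± 0.23 and Ebp by -0.33 ± 0.22. Sc5d, not well above background on the Ifnar1-/- arrays, was at least 1.26-fold lower. Sc5d lay at 5.39 and 5.84 on the Ifnar1+/+ arrays. Its difference was -0.54 with all arrays and -0.33 without Ifnar1+/+ array 2. The cholesterol call was lost without Ifnar1+/+ array 2 (0.00, adjusted p = 0.83) and without Ifnar1-/- array 2 (-0.16, adjusted p = 0.89); its median was -0.35 without Ifnar1+/+ array 1 and -0.47 without Ifnar1-/- array 1.

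The lists of proliferation genes, Wnt/beta-catenin targets and stem cell markers passed as higher, with 0 members of each passing over the list alone. All 28 proliferation and cell cycle genes had a higher mean in the Ifnar1-/- samples, with a median of 0.53. The helicase subunit genes Mcm7, Mcm5 and Mcm6, needed to start DNA replication, differed by 0.78 ± 0.22, 0.82 ± 0.25 and 0.87 ± 0.27 (SE). The list had an adjusted p = 1.2e-07, and an adjusted p = 0.52 with an estimated correlation. Its median was 0.77 on Ifnar1-/- array 1 and 0.27 on array 2, and it was 0.27 (adjusted p = 0.0033) without array 1. The 22 Wnt/beta-catenin targets, 11 of them shared with other lists, had a median of 0.28 (adjusted p = 0.0055; adjusted p = 0.51 with an estimated correlation), with 16 higher and 6 lower. Tiam1, an activator of the GTPase Rac, differed by 1.06 ± 0.23 and is also on the list of genes near Ifnar1 on chromosome 16. The receptor gene Tnfrsf19 differed by 1.14 ± 0.46 (0.43 without Ifnar1-/- array 2) and the ion cotransporter gene Slc12a2 by 0.57 ± 0.24. This call was lost without Ifnar1-/- array 2 (0.14, adjusted p = 0.36) and with shared members left out (0.15, adjusted p = 0.091); the median was 0.14 without Ifnar1+/+ array 2 and 0.42 without Ifnar1+/+ array 1. The 15 stem cell markers, 9 of them shared with other lists, had a median of 0.29 (adjusted p = 0.022; adjusted p = 0.41 with an estimated correlation), with 11 higher and 4 lower. Lrig1, a restraint on growth factor receptors, differed by 0.83 ± 0.23 and the water channel gene Aqp4 by 1.05 ± 0.42, while Prom1, not well above background on the Ifnar1-/- arrays, was at least 1.32-fold lower. Prom1 lay at 5.41 and 5.96 on the Ifnar1+/+ arrays, so this bound rests chiefly on array 2. Its difference was -0.67 with all arrays and -0.42 without Ifnar1+/+ array 2. The stem cell call was lost without Ifnar1-/- array 2 (0.25, adjusted p = 0.17) and with shared members left out (0.34, adjusted p = 0.097), and the median was 0.47 without Ifnar1+/+ array 1.

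Paneth cells secrete antimicrobial peptides at the base of the crypt. All 10 of their markers had a higher mean in the Ifnar1-/- samples, with a median of 1.10, an adjusted p = 3.0e-05, and an adjusted p = 0.51 with an estimated correlation. Only Habp2, a serine protease gene, passed over the list alone (1.05 ± 0.23, SE); the defensin gene Defa20 (1.15 ± 0.40) and the lysozyme gene Lyz1 (0.71 ± 0.25) followed. Defensin genes are near-identical to one another, so their single values are uncertain. The list median was 1.60 on Ifnar1-/- array 1 and 0.23 on array 2. Without array 1 the median was 0.23 and the call was lost (adjusted p = 0.12), and without array 2 it was 1.64.

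Inflammatory and stress lists had lower values. All 16 inflammatory cytokine and NF-kB target genes were lower, with a median of -0.53 (adjusted p = 1.0e-05; adjusted p = 0.41 with an estimated correlation) that was -0.51 and -0.58 on the Ifnar1-/- arrays. Ccl4, a chemokine gene, was the 1 member to pass over the list alone; it was not well above background on the Ifnar1-/- arrays, at least 1.55-fold lower. The cytokine genes Il18 and Il33 differed by -0.95 ± 0.25 and -1.04 ± 0.34 (SE). This median was -0.24 without background correction and -0.12 with no filter on dim probes. Of 21 endoplasmic reticulum stress genes (median -0.29, adjusted p = 0.0069; adjusted p = 0.41 with an estimated correlation), the chaperone gene Hyou1 passed over the list alone (-1.33 ± 0.26). Sel1l (-0.66 ± 0.23) and Ern2, a stress sensor of mucus-secreting cells (0.83 ± 0.27), did not; the list median was -0.10 without Ifnar1-/- array 1 and -0.49 without array 2. The 15 mucosal antimicrobial genes had a median of -0.43 (adjusted p = 0.034; adjusted p = 0.53 with an estimated correlation). The lectin gene Reg3b differed by -2.35 ± 0.66, the protease inhibitor gene Slpi by -1.91 ± 0.61 (-0.89 without Ifnar1+/+ array 1, -2.92 without array 2) and the antibody transporter gene Pigr by -0.70 ± 0.25. That call was lost without Ifnar1-/- array 2 (-0.09, adjusted p = 0.67) and with no filter on dim probes (-0.04, adjusted p = 0.075), and the median was -0.86 without Ifnar1-/- array 1 and -0.19 without Ifnar1+/+ array 2. The 11 senescence-associated secretory genes had a median of -0.53 (adjusted p = 0.028; adjusted p = 0.49 with an estimated correlation), with Il15 at -0.78 ± 0.25, the cell cycle inhibitor gene Cdkn2b at -0.70 ± 0.23 and the adhesion gene Icam1 at -0.60 ± 0.25. Their call was lost without Ifnar1+/+ array 1 (0.23, adjusted p = 0.54), without Ifnar1-/- array 2 (-0.31, adjusted p = 0.26) and with shared members left out (-0.50, adjusted p = 0.15).

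The other lists did not pass, although some did with an array left out. The goblet cell markers (17 genes, median 0.16, adjusted p = 0.46) were at 0.67 on Ifnar1-/- array 1 and -0.31 on array 2. In that list Clca1, a secreted mucus component, was lower when adjusted over the list alone (-1.34 ± 0.23, SE), while Foxa3 (0.81 ± 0.26) and Slc12a8 (0.63 ± 0.24) were not called; the list passed as lower without array 1 (-0.29, adjusted p = 0.030) and as higher without array 2 (0.66, adjusted p = 0.0045). The p53 targets had a median of 0.00 (26 genes, adjusted p = 0.70), the enteroendocrine markers -0.06 (16 genes, adjusted p = 0.46) and the tight and adherens junction genes -0.10 (16 genes, adjusted p = 0.33). The tuft cell markers had a median of -0.41 (7 genes, adjusted p = 0.18), or -0.16 with the 1 member not above background at its bound, and passed as lower without Ifnar1+/+ array 2 (-0.43, adjusted p = 0.030). The immediate-early and heat-shock genes had a median of -0.07 (18 genes, adjusted p = 0.083) and passed as lower without Ifnar1+/+ array 2 (-0.25, adjusted p = 0.028) and without Ifnar1-/- array 2 (-0.18, adjusted p = 0.0094). The colon region genes had a median of -0.19 (11 genes, adjusted p = 0.091) and passed as lower without Ifnar1+/+ array 1 (-0.32, adjusted p = 0.00055) and without Ifnar1-/- array 2 (-0.61, adjusted p = 0.045). The endothelial and blood cell markers had a median of 0.18 (7 genes, adjusted p = 0.28), which was 0.00 without Ifnar1+/+ array 1 and 0.45 without array 2. The exocrine pancreas markers had a median of 0.20 (5 genes, adjusted p = 0.83), which was 0.37 without Ifnar1-/- array 1 and 0.03 without array 2. The 29 genes near Ifnar1 on chromosome 16 had a median of 0.02 (adjusted p = 0.46), or -0.05 without Ifnar1+/+ array 1, and 2 were higher when adjusted over the list alone, Tiam1 and the chloride channel gene Clic6 (1.26 ± 0.28), while Atp5o was not called (-0.97 ± 0.24). The 3 Y-linked genes were too few for the list test.

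None of the genes with the smallest p-values in either direction passed over all genes tested, each with an adjusted p = 0.40 except Oas2. They were taken from genes whose groups did not overlap and whose means differed by at least 1 log2 unit. Higher in the Ifnar1-/- samples were Txndc12, an oxidoreductase gene of the endoplasmic reticulum (1.60 ± 0.31, SE), Wfdc2, a secreted protease inhibitor gene (2.83-fold), Tnfrsf18, a co-stimulatory receptor gene (at least 1.84-fold), and the lipoprotein receptor gene Vldlr (1.34 ± 0.26). The elongation factor gene Ell3, the growth factor gene Fgf22, the matricellular gene Ccn2, St3gal3, Mpp3 and Pxylp1 lay between 1.08 and 1.27. Lower, beside the interferon-stimulated and T cell genes above, were Hdhd3 (-1.57 ± 0.26), Dbp, a transcription factor gene of the circadian clock (-1.53 ± 0.24), and Clic5, a chloride channel family member of the brush border (-1.44 ± 0.22). Without background correction 15 of the 20 genes with the smallest p-values, 10 in each direction, had a difference over 1.5 times smaller. For 5 of them it was over 2.5 times smaller: Wfdc2 (0.55), Ccn2 (0.45), Dbp (-0.59), Tnfrsf18 and Cd3d. The probe that stood for Tnfrsf18 was not well above background on either Ifnar1+/+ array, and with another of its probes in its place the difference was 0.13 without Ifnar1-/- array 1 and 0.62 without array 2. Wfdc2 and Ifnar2 were not well above background on 1 Ifnar1+/+ array, Dbp, Cd3g, Ciita, Col6a2 and Sparc on 1 Ifnar1-/- array, and Ms4a6d on 1 array of each group, so their differences rest partly on signals at background. With an array left out, 45 of 108 genes chosen by the rule fixed beforehand moved over 1.5 times, among them H2-DMa, H2-DMb1, Ciita, Socs3, Stat2, Aqp4, Icam1, Defa20, Sis, Acaa1a, Eci2, Cyp2c65, Cyp2c55, Reg3b, Il33, Fcer1g, Ms4a6d, Col6a2 and Sparc.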

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

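The alternative that leaves out list members held by other lists was chosen after the data were examined; the others were planned. No gene passed in either direction under any planned setting that kept all 4 arrays; with an array left out, 0 to 13 genes passed as lower and 0 to 3 as higher. Of the 32 lists tested, 22 passed, and 16 to 23 under the other settings, 18 with shared members left out, but 0 with an estimated correlation and 0 by fry, which does not compare a list with other genes. The interferon-stimulated list had an adjusted p = 0.414 with an estimated correlation and 0.267 by fry. Both tests use the same fit, so the median of -1.01 could not change. Both allow for genes that vary together, but the estimated-correlation test also called 0 of 20 simulated lists whose genes varied independently. Its lack of calls therefore cannot show whether the genes of a list vary together. Signal over background limits dim genes: without background correction the median of this list was -0.48. Over all settings it ran from -1.18, without Ifnar1-/- array 2, to that value. Median scaling moved the median of all genes from 0.03 to 0.11, and the list lay at -1.08 relative to that. With the replicate number as a block, a replicate block fit, 0 genes and 23 lists passed. Same-numbered deviations correlated at -0.05 over genes. This shows no common shift but cannot tell whether same-numbered samples share a litter or day. The B and plasma cell list lost its call under the block (adjusted p = 0.057), and the immediate-early (0.049) and colon region (0.044) lists gained one, as they did under median scaling (0.044 and 0.025), and the first with the strict filter (0.044) and the second with shared members left out (0.039).

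Results with no call, and the small intestine region list, which had one, turned direction in places, and the cause was not tested. The pancreas list was at -0.0035 with no filter and its direction by fry was lower at a median of 0.20; the p53 list was at 0.036 with shared members left out. With an array left out, Csnk1a1 ran from -0.24 to 0.062, Ifnar2 from -0.51 to 0.36, Kdm5d from -0.092 to 0.13, the p53 list from -0.093 to 0.15, the goblet list from -0.29 to 0.66, the enteroendocrine list from -0.20 to 0.12, the small intestine region list from -0.75 to 0.14 and the junction list from -0.26 to 0.057. Medians changed sign, though the test's direction did not, for MHC class II (0.04 without Ifnar1-/- array 1), senescence (0.23), tuft cell (0.03) and chromosome 16 genes (-0.046, these 3 without Ifnar1+/+ array 1). With the strict filter, too few T cell, macrophage, B cell, endothelial and pancreas markers were left to test.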

Other observations

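The tests on the interferon-stimulated genes, the gene-by-gene change that decides the Paneth cell scaling test and the comparison of region genes with enterocyte genes were chosen after the result was seen, and the proximal, distal and clock genes were listed after the values of Fabp6, Tmprss15 and Dbp had been seen. Genes that the report does not name were also chosen after their values were seen. Among genes of ileal bile acid handling, both subunits of the basolateral bile acid exporter had lower means in the Ifnar1-/- samples, beside Fabp6: Slc51b by -1.26 ± 0.26 and Slc51a by -1.03 ± 0.32 (log2, SE, n = 2 per group). Neither passed over all genes tested (adjusted p = 0.40 and 0.50), and the groups did not overlap for either. Fgf15, a bile acid-induced hormone gene, differed by -1.17 ± 0.95 (adjusted p = 0.68), and its groups overlapped. Tmprss15, the duodenal protease that activates trypsinogen, differed the other way (1.71 ± 0.45, adjusted p = 0.49), at 6.62 and 8.05 on the Ifnar1-/- arrays against 5.73 and 5.52.

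Of the clock genes measured, Dbp (-1.53 ± 0.24) and Nr1d1 (-1.04 ± 0.24), which encodes a repressor in the clock's feedback loop, had lower means. Other genes of the clock did not share this. Per1 (0.14 ± 0.25), Per2 (-0.08 ± 0.23) and Arntl (-0.02 ± 0.25) lay near 0. Nr1d2 (0.34 ± 0.46), Hlf (0.23 ± 0.23), Tef (0.16 ± 0.22) and Ciart (0.30 ± 0.37) had higher means. Of these, Nr1d2 lay at 6.72 and 5.25 on the Ifnar1-/- arrays against 5.65 and 5.64. The groups overlapped for Ciart, and Hlf, at 5.33 to 5.70, lay close to background. The other 5 clock genes lay between -0.30 and -0.12, and none of the clock genes passed (Nr1d1, adjusted p = 0.42). Among the 29 neighbours of Ifnar1 on chromosome 16, 6 had an unadjusted p under 0.05, or 20.7% against 9.54% of all genes (Fisher's exact test, two-sided, exact p = 0.0523). Without Ifnar1+/+ array 2 the genes that passed as lower included Dcn (-2.82), which lay at 11.13 and 8.63 on the Ifnar1+/+ arrays.

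Interferon-stimulated genes were lower on both Ifnar1-/- arrays, and the design offers loss of the type I interferon receptor as a biological explanation, a hypothesis with no test of its own here. A single deviant array is argued against, since the array nearer to the Ifnar1+/+ mean had a median of -0.71 (95% bootstrap interval -1.20 to -0.51). The intervals here and below resample the genes of a list on fixed arrays. They measure the spread over genes and not the spread between samples. Scaling or background correction is argued against too, the weakest of 5 settings giving -0.50 relative to all genes (-0.81 to -0.40). Fewer lymphocytes in the Ifnar1-/- preparations may account for part and cannot be told apart. Lymphocyte markers differed by 0.0039 between the Ifnar1+/+ arrays (-0.21 to 0.09), where the interferon-stimulated genes differed by 0.36 (0.31 to 0.45). Between the Ifnar1-/- arrays lymphocyte markers differed by 0.70 (0.22 to 1.18). Interferon-stimulated genes differed there by 0.23 in the same direction, with an interval that includes 0 (-0.05 to 0.54). Absorptive enterocyte genes were also lower on both Ifnar1-/- arrays (-1.28 and -0.42), and a lower share of these cells was not tested for this pattern. The 4 arrays make 3 splits into pairs, too few for a share under 0.05; 1 of the 3 splits, the real one, gave as many lists past the threshold, 22 against at most 12, and the other 2 passed enterocyte genes too (adjusted p = 1.5e-06 and 7.2e-05) and 1 of them interferon-stimulated genes (adjusted p = 0.0030).

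All 10 Paneth cell genes were higher on Ifnar1-/- array 1 than on array 2, by a median of 1.28 (0.28 to 2.68), from 17.2-fold for Defa21 and 11.5-fold for Defa26 through 3.22-fold for the angiogenin Ang4 to 1.21-fold for Mmp7 and 1.16-fold for Lyz1 and Habp2. Cross-hybridisation among defensins is argued against as the whole cause, since the 6 markers that are not defensins were all higher there, by a median of 0.69 (0.21 to 1.52). Scaling or background correction is argued against too: the weakest of 5 settings gave a median of 1.22 (0.22 to 2.67), and it moved the genes by -0.14 to -0.02 where -0.79 would bring the median to 0.5. A larger share of crypt cells may be the source but cannot be told apart. Against array 2, enterocyte genes were lower (-0.96) and proliferation genes higher (0.46). Yet stem cell markers lay at -0.19 (-0.34 to 0.34) and Wnt targets at -0.34 (-0.61 to -0.14). These lists share members, so the values are not separate observations. Of the stem cell markers, 6 were higher on array 1, Lgr5 and Olfm4 among them, and 9 were lower. Goblet cell markers were higher too (0.78), and a change in secretory cells of that sample was not tested.

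The lower Fabp6, Slc51a and Slc51b and the higher Tmprss15 could come from a more proximal stretch of small intestine in the Ifnar1-/- preparations. The distal genes had a median of -0.77 (-1.10 to -0.34), but they include Slc51a, Slc51b and Fgf15, so this is no separate support. By array, the proximal genes lay at -0.76 (-0.96 to -0.28) on Ifnar1-/- array 1 and at 0.07 (-0.15 to 0.67) on array 2. The distal genes lay at -0.83 and -0.44 there. Over both arrays the proximal genes had a median of -0.38 (-0.48 to 0.02), below the bound set for them. That bound left out that enterocyte genes in neither set were lower too, at -0.80: relative to these the proximal genes lay at 0.42 (0.29 to 0.87) and the distal genes at 0.03 (-0.32 to 0.51). A regional shift therefore cannot be told apart from a lower share of enterocytes. Loss of Ifnar1 itself remains an untested explanation.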
